A study of Mus musculus with 4 samples.

How the data were processed

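Single-cell RNA sequencing was done on transplanted mammary tumours of mice grown from Py8119, a mesenchymal carcinoma line derived from a mammary tumour of an MMTV-PyMT mouse on the C57BL/6 background. There were 4 libraries, 2 from control tumours and 2 from tumours in which Sema4d had been knocked down by a short hairpin RNA (shRNA). Per the labels' protocols, the tissue was digested with a tumour dissociation enzyme kit for 30 min at 37 °C, passed through strainers of 70 and 40 µm and freed of red cells by lysis. Cells were encapsulated in droplets with the DNBelab C Series kit and sequenced on a DNBSEQ-T7, with a read 1 of 30 bp that holds 2 barcode parts of 10 bp and a 10-bp unique molecular identifier (UMI), and a read 2 of 100 bp for the transcript.

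Each deposited file holds a sparse matrix of raw UMI counts, 1 row per gene symbol and 1 column per cell, which the authors did not normalise as far as the values show, since all are whole numbers and libraries sum to different totals. PISA 1.0 wrote the matrices, per the file headers. STAR 2.5.1b is named in the submitters' processing notes, which name the builds GRCh38 and mm10 without saying which was used for what. The symbols in the files are mouse symbols. The gene annotation behind the counts, the cell calling and the use of strand are not given in the sources used here, so genes that share sequence with a close copy are uncertain throughout. Every deposited cell had at least 1000 UMIs. Coordinates are of GRCm38 from GENCODE M21, matched by symbol, with 139 of the 141 named genes matched.

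The 4 matrices listed 20888 to 22216 genes each, 23635 in all and 19202 in every library, of which 13 were mitochondrially encoded. No pair of libraries was a copy of another. Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept, which left 45062 of 45220. Doublets were scored in each library with scrublet (in scanpy 1.11.5, expected rate 0.06). Its automatic threshold marked 0.766% and 1.51% of cells in the control libraries and none in the shRNA libraries. Where it marked under 0.5%, the cells with the highest scores were marked up to the expected rate, which gave 6.00% in each shRNA library, so the rule differed between groups. Marked cells were clustered with the others and left out of every count, which left 43400 cells.

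Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours were used. Leiden clustering (igraph version, called from scanpy) at resolution 1 gave 25 clusters, without batch integration. Clusters were named from marker lists fixed in advance, by the mean log2 level of a list relative to the other clusters. The scoring limits were set after the data had been seen. A class other than tumour needed a score of at least 1 and at least 3 of its own markers at 20 CPM or more. Tumour-like clusters were named from those that no other class claimed, and no tumour score was asked of them. They needed at least 3 tumour markers at 20 CPM or more and at least 3 times the macrophage level, with every other class scoring below 0.75. A cluster stayed unnamed if it carried markers of both macrophages and tumour, if over 20% of its cells were marked as doublets at a score below 2, if its median UMI count relative to its library was below 0.333 without an own marker among its top 10 genes, if it carried normal mammary genes, or if it had under 20 cells. Cells left unnamed were 15.6% and 10.1% of the control libraries and 3.74% and 5.31% of the shRNA libraries. A cluster of few UMIs, whose top 10 genes were all mitochondrially encoded, took 6.61% and 3.99% against 1.60% and 2.24%. A cluster of macrophage markers rich in doublets took 4.99% and 4.75% against 1.32% and 2.17%, and a cluster of mixed macrophage and tumour markers 2.92% and 1.09% against 0.293% and 0.122%. T and NK-like cells were clustered again by themselves to name subtypes, again with a score of at least 1. Sub-clusters left out as mixed or unnamed are not in any subtype. Mixed ones, with over 20% of cells marked as doublets, were moved out of the class to the unnamed cells. Unnamed ones stayed in the class and in the total of the subtype shares, at 10.9% to 20.8% of it per library.

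For each class with at least 50 cells in every library, raw counts were summed per library and tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using filterByExpr, TMM factors and the robust quasi-likelihood test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes of the class at 0.05. Tumour-like, macrophage or monocyte-like and T and NK-like cells met this. Dendritic, neutrophil, fibroblast and endothelial-like cells did not and are given as values. Cell numbers per class were tested with the same tool with the log of the library's cells as offset. Shares of a single library have exact Clopper-Pearson intervals at 95%, which cover counting error only. Up to 26 gene lists were tested per class with camera at a preset correlation of 0.01, repeated with an estimated correlation and with fry, and adjusted over the lists of the class. The difference of the shRNA effect between classes was tested in edgeR with an interaction term and the library as a block.

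Genes are named by a rule fixed in advance. It takes Sema4d, its receptors Plxnb1, Plxnb2 and Cd72 as values, up to 10 higher and 10 lower genes of largest change with an adjusted p under 0.05 in tumour-like and in macrophage or monocyte-like cells (5 and 5 in T and NK-like cells), and up to 4 members of each called list with the smallest p. Genes of largest change needed a mean of at least 20 CPM, no overlap between the groups, a symbol that is neither a predicted gene nor an antigen receptor segment, and no place on another class's marker list. The sample groups, tests, gene lists, cell markers, naming rule and most alternatives were chosen before the data were examined. The choices made later are named where they are used.

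Free RNA, released by other cells and captured in every droplet, was estimated for each class and library as the median level of the markers of another class relative to that class. A gene was called mostly free RNA if at least 50% of its level in a class could be accounted for this way. Macrophage markers stood in tumour-like cells at 1.31% and 1.57% of their macrophage level in the control libraries and at 0.643% and 0.697% in the shRNA libraries. For shares of cells with a UMI, each cell was also thinned to 1000 UMIs, and no cell was below that depth.

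The tests were tried on simulated data drawn from the real libraries' means and sizes. In 14446 genes of tumour-like cells edgeR recovered 46.2%, 75.8% and 97.0% of genes changed by 0.5, 1 and 2 on the log2 scale, in 12512 genes of macrophage or monocyte-like cells 17.9%, 69.7% and 98.5%, and in 8123 genes of T and NK-like cells 14.1%, 46.3% and 93.9%. Of its calls, 13.8%, 19.2% and 8.93% were false, a larger share than the adjusted p limit of 0.05 allows. With DESeq2 1.42.0 the false shares were 10.3%, 9.01% and 0%. Camera found the 1 changed list in each class, and of its 2 calls in tumour-like cells 1 was false. The simulated genes varied independently of each other, so this does not give camera's false calls where list members vary together. In the lists called in tumour-like cells the estimated correlation ranged from -0.0145 to 0.877. In the interaction test, 14.4% of the calls between tumour-like and macrophage or monocyte-like cells and 7.14% of those between tumour-like and T and NK-like cells were false. It recovered 7.69%, 51.6% and 87.7% of differences of 0.5, 1 and 2 in the first comparison and 0%, 11.9% and 50.8% in the second. The simulated test was adjusted over all 15090 and 14001 genes, while the reported one was adjusted over the 128 and 90 named genes only. The simulated shares of false calls and of recovered differences therefore do not carry over to it. What the reported test misses was not simulated, so a difference that is not called is not shown to be absent.

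The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Neither batch nor date is given. Alternatives were other size factors, DESeq2, no low-count filter, the replicate number as a block, each library left out, doublet calls kept, stricter cell limits, other clustering resolutions and equal cell numbers. Alternatives chosen after seeing the data were the same doublet share in every library, low-UMI and mixed clusters added, clusters rich in nuclear RNA left out, genes that overlap ribosomal RNA or are mitochondrial left out, genes of mostly free RNA left out, and bias-adjusted dispersions.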

Results

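The study asked what semaphorin 4D made by the tumour cells themselves does in a mouse model of triple-negative breast cancer. Sema4d encodes a transmembrane semaphorin that binds plexin-B1, plexin-B2 and CD72. Tumours grown from Py8119 cells were taken apart and sequenced cell by cell, with 2 control libraries and 2 libraries from tumours whose cells carried a Sema4d shRNA. The libraries held 10874 and 10598 control cells and 10575 and 13173 shRNA cells, with 101909637, 83513906, 113904173 and 119758159 UMIs. The median depth was 6743 and 5690 UMIs per cell in the control libraries and 8180 and 6951 in the shRNA libraries. After filtering, 43400 cells were compared, among them 26672 tumour-like, 10162 macrophage or monocyte-like and 2022 T and NK-like cells.

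Sema4d was counted at a low level in the tumour-like cells and was lower in both shRNA libraries than in both controls. Its level was 7.14 ± 0.527 CPM (SD, n = 2) in the control and 4.66 ± 1.15 CPM (SD, n = 2) in the shRNA tumours, a log2 change of -0.56 (SE 0.18), which left 65.2% of the control level. The single libraries stood at 6.77 and 7.52 CPM against 3.84 and 5.47 CPM. The gene lies on chromosome 13 from 51685529 to 51793747 on the minus strand (GRCm38). For this gene fixed in advance edgeR gave an unadjusted p = 0.0146, while an exact permutation test of 2 against 2 libraries cannot go below 0.333. Adjusted over all genes, edgeR gave an adjusted p = 0.258. Free RNA could account for 16.7% of the Sema4d UMIs in tumour-like cells, and with it subtracted 66.5% of the control level was left. Without control replicate 2 the change was -0.49 and the unadjusted edgeR p = 0.0861, again against the exact permutation limit. The change was -0.31 without shRNA replicate 1 and -0.86 without shRNA replicate 2.

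A Sema4d UMI was found in 7.58% and 7.26% of the tumour-like cells of the control libraries (exact 95% intervals 6.90 to 8.30 and 6.58 to 7.99) and in 4.50% and 5.31% of those of the shRNA libraries (4.03 to 5.0 and 4.85 to 5.81). Thinned to 1000 UMIs per cell, the shares were 0.694% and 0.770% against 0.354% and 0.562%. Fibroblast-like cells, which should make little of it, had a Sema4d UMI in 6.25%, 5.26%, 2.63% and 0.840% of cells, on 7 UMIs in all, at median depths of 3148 to 3460 UMIs against 8798 to 10639.5 in the tumour-like cells. Thinned to 1000 UMIs, the fibroblast-like shares were 0.971%, 0.479%, 1.85% and 0.358%. Both the full and the thinned shares overlap with those of the tumour-like cells, and 7 UMIs are too few to say whether the tumour-like cells lie above this background.

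**Figure D1:**
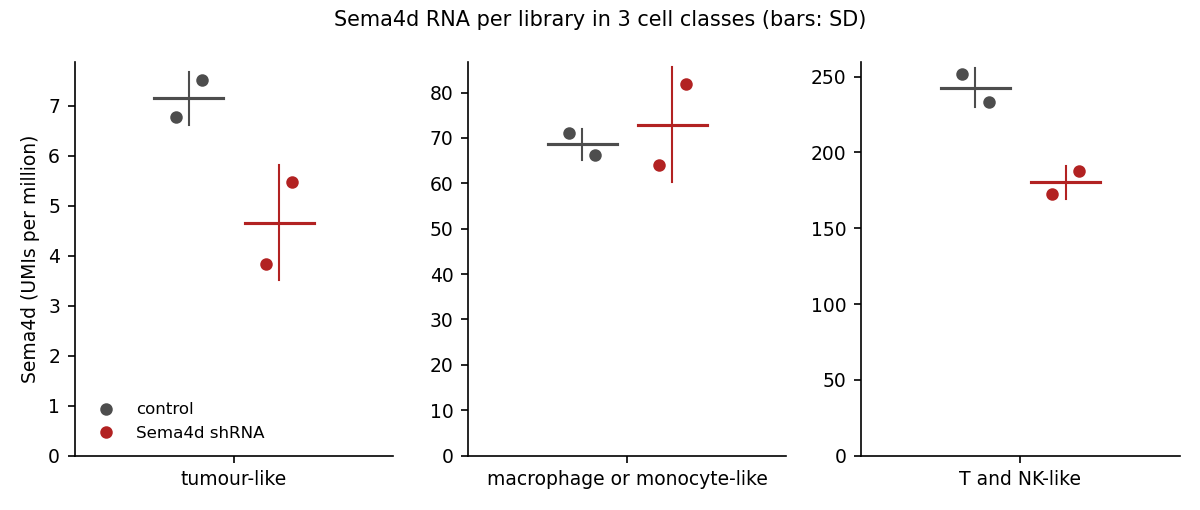
Sema4d level in CPM of the summed cells of each library, for tumour-like, macrophage or monocyte-like and T and NK-like cells, with a point per library and the mean and SD of each group. Tumour-like cells stood at 6.77 and 7.52 CPM in the control and 3.84 and 5.47 CPM in the shRNA libraries, and T and NK-like cells had the highest level, 243 CPM in the control.

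Sema4d stood higher in the immune classes tested than in tumour-like cells. T and NK-like cells had 243 ± 13 CPM (SD, n = 2) in control and 180 ± 10.7 CPM (SD, n = 2) in shRNA tumours, a log2 difference of -0.41 with an edgeR adjusted p = 0.253. Their single libraries stood at 252 and 233 CPM against 173 and 188 CPM, so both shRNA libraries lay below both controls here too. Adjusted over all genes, Sema4d passed in neither tumour-like nor T and NK-like cells. Macrophage or monocyte-like cells had 68.6 ± 3.37 and 72.9 ± 12.6 CPM (SD, n = 2 each), a log2 difference of 0.17 with an adjusted p = 0.726. The effect on Sema4d differed between macrophage or monocyte-like and tumour-like cells by 0.75 (SE 0.14, edgeR interaction adjusted p = 2.5e-04), and between T and NK-like and tumour-like cells by 0.21 (adjusted p = 0.569), or -0.0126 without shRNA replicate 1. Of the receptors, Plxnb2 (chromosome 15, 89155549 to 89180788) stood at 69.8 ± 4.95 and 57.1 ± 4.26 CPM in tumour-like cells and at 96.9 ± 4.67 and 70.4 ± 6.11 CPM in macrophage or monocyte-like cells (SD, n = 2 each; adjusted p = 0.302 and 0.268). Plxnb1 (chromosome 9, 109095389 to 109119917) stood at 1.43 ± 0.0463 and 1.71 ± 0.0380 CPM in tumour-like cells. Cd72 (chromosome 4, 43446462 to 43454628) was mainly in macrophage or monocyte-like cells, at 171 ± 26.9 and 166 ± 35.9 CPM (adjusted p = 0.969). None of the receptors passed the test over all genes in these classes.

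The shRNA tumours held a larger share of tumour-like and T and NK-like cells and a smaller share of macrophage or monocyte-like cells in every library, but no share passed the test once adjusted. Tumour-like cells made up 51.5% ± 0.683 of the control and 71.2% ± 3.48 of the shRNA libraries (SD, n = 2; log2 0.47, edgeR adjusted p = 0.199). Macrophage or monocyte-like cells made up 30.8% ± 5.61 and 16.5% ± 0.178 (log2 -0.91, adjusted p = 0.169). T and NK-like cells made up 3.0% ± 0.646 and 6.09% ± 1.88 (log2 1.02, adjusted p = 0.169). Dendritic-like cells were 0.833% and 0.693%, neutrophil-like cells 0.447% and 0.197%, fibroblast-like cells 0.389% and 0.675% and endothelial-like cells 0.165% and 0.202%, with adjusted p from 0.199 to 0.552. Red cell lysis and the enzymatic digestion can set such shares, and 3.74% to 15.6% of a library's cells were left unnamed, more in the controls.

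Among immune cells alone, T and NK-like cells were 8.77% ± 3.06 in control and 25.7% ± 5.95 in shRNA tumours (SD, n = 2), 2.94-fold higher, with an edgeR adjusted p = 0.0546. The single libraries stood at 10.9% and 6.60% (exact 95% intervals 9.90 to 12.0 and 5.85 to 7.42) against 21.5% and 29.9% (19.8 to 23.3 and 28.3 to 31.6). Macrophage or monocyte-like cells were 87.5% ± 3.81 and 70.5% ± 6.45 of immune cells (adjusted p = 0.448). The adjusted p of the T and NK-like share was 0.0203 with TMM factors on cell numbers and 0.0481 at the higher clustering resolution. Within the T and NK-like cells, NK cells were 12.0% ± 3.30 in control and 20.4% ± 5.05 in shRNA tumours (log2 0.77, adjusted p = 0.343). CD8 T cells were 37.0% ± 4.31 and 36.8% ± 13.1, cells scored as cycling 10.7% and 11%, other CD4 T cells 16.9% and 13.5%, and regulatory T cells 4.87% and 3.55%, with adjusted p from 0.649 to 0.999. The cells scored as cycling include 3 and 3 control and 8 and 5 shRNA cells of a small sub-cluster whose top genes are led by granzymes. The whole T and NK-like class held 372 and 265 control and 471 and 914 shRNA cells.

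**Figure D2:**
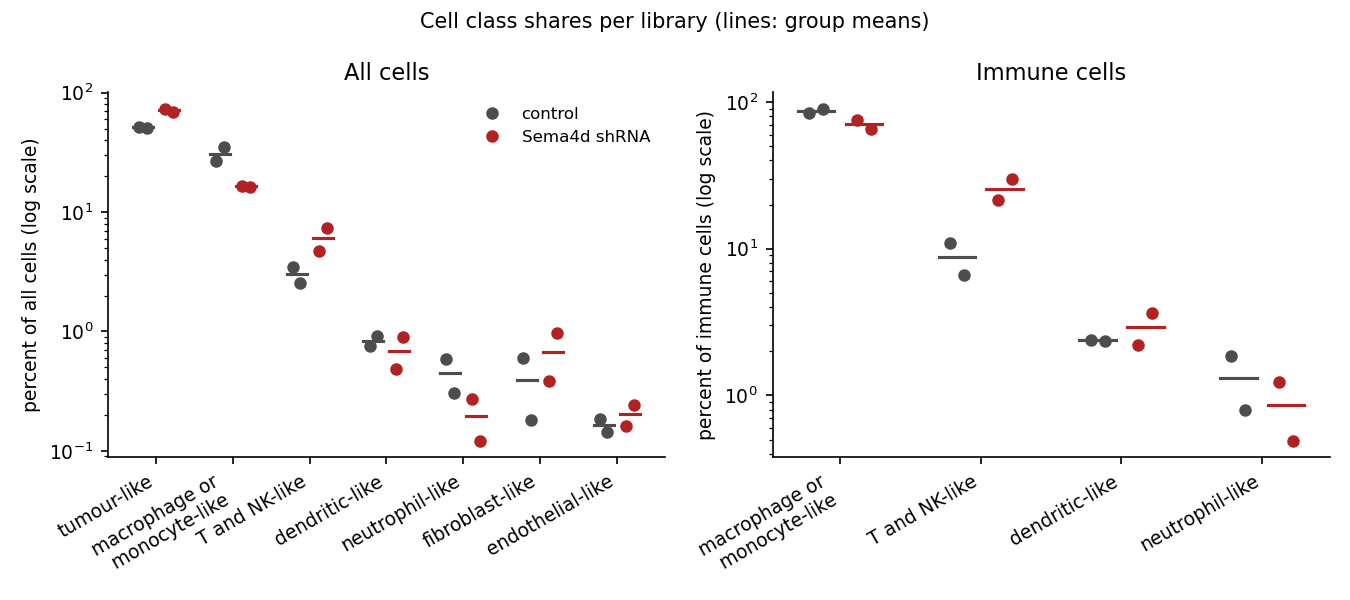
Share of each cell class in percent, by library, with a point per library for the control and shRNA groups. T and NK-like cells were 10.9% and 6.60% of immune cells in the control and 21.5% and 29.9% in the shRNA libraries.

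In tumour-like cells the Sema4d shRNA went with 12 genes higher and 67 lower out of 14556 tested (edgeR, adjusted p under the limit). The strongest rise was that of Ppp2cb, a catalytic subunit of protein phosphatase 2A, from 24.7 ± 0.0760 to 47.7 ± 1.82 CPM (SD, n = 2 each; log2 1.00, SE 0.08, adjusted p = 0.0037). Rab21, a small GTPase of endosomal traffic, rose by 0.88 on the log2 scale (SE 0.08, adjusted p = 0.0043), and Ybx3, a cold-shock-domain RNA-binding protein, rose from 329 ± 17.4 to 499 ± 50.5 CPM (log2 0.65, adjusted p = 0.028). Inhba, which encodes the βA subunit of activin, rose from 37.3 ± 0.640 to 52.5 ± 0.685 CPM (log2 0.54, adjusted p = 0.027). Ppp1r15a, which directs the dephosphorylation of eIF2α under stress, rose by 0.49 (adjusted p = 0.043), Ier5l by 0.53 and Tecpr2 by 0.48. Erdr1 rose by 0.84 (adjusted p = 0.013) but has near-identical copies on the sex chromosomes and is uncertain. The other 4 higher genes, named here after their values were seen, were Sirt1, Gm12868, 1810011O10Rik and Gzmb, the last of which could come from free RNA of lymphocytes. Ppp2cb and Rab21 passed with any library left out, and the last 4 genes were not tested in this way. Without control replicate 1 the adjusted p was 0.0896 for Inhba, 0.13 for Ier5l, 0.141 for Ppp1r15a and 0.196 for Tecpr2, and without control replicate 2 it was 0.0599 for Erdr1, 0.177 for Ybx3, 0.197 for Inhba, 0.153 for Ier5l, 0.243 for Ppp1r15a and 0.220 for Tecpr2. Ppp2cb lies on chromosome 8 from 33599625 to 33619441 and Rab21 on chromosome 10 from 115287084 to 115315594. Both also stood higher in host cells, by 0.81 each on the log2 scale in macrophage or monocyte-like cells. In T and NK-like cells they stood higher by 1.07 and 1.06. Erdr1 did not follow, at -0.04 and 0.11 in these 2 classes.

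Among the lower genes of the tumour-like cells' own RNA, the imprinted noncoding RNA H19 fell from 165 ± 4.37 to 94.2 ± 5.76 CPM (SD, n = 2 each; log2 -0.76, SE 0.08, edgeR adjusted p = 0.013). Prkcdbp, a coat protein of caveolae, fell from 114 ± 2.41 to 67.9 ± 5.92 CPM (log2 -0.70, adjusted p = 0.014), and Tspan15, a tetraspanin partner of the protease ADAM10, from 38.8 ± 0.729 to 23.1 ± 0.178 CPM (log2 -0.70, adjusted p = 0.013). Ccdc85b changed by -0.90, Heg1 by -0.77 and the glutathione transferase Gstp1, which has a close paralog and is uncertain, by -0.82. H19, Tspan15 and Heg1 are among the top genes of cluster 9, which held 8.30% and 8.90% of the tumour-like cells in the control and 2.45% and 2.03% in the shRNA libraries, and H19 also of cluster 4 (23% and 26.5% against 4.03% and 5.33%), so their values do not show a change within cells. Without control replicate 2 the adjusted p was 0.0521 for Prkcdbp, 0.0646 for Tspan15 and 0.100 for Gstp1. Of the 67 lower genes, 38 were ones that free RNA of other cells could account for, among them Arg1, the arginase of myeloid cells (47.2 ± 3.83 to 20.4 ± 0.823 CPM, log2 -1.16, adjusted p = 0.0037), and the Fc receptor chain Fcer1g (log2 -1.08). Macrophage RNA made up 20.6% of all UMIs in the control and 8.97% in the shRNA libraries. Without genes of mostly free RNA, 11 were higher and 29 lower. Of these genes 38 were also tested in macrophage or monocyte-like cells, and 33 changed in the same direction there.

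On all 4 libraries the gene lists of proliferation, interferon response and stress stood higher in tumour-like cells of the shRNA tumours, while mitochondrially encoded genes and MHC class II genes stood lower. All 51 G2 and M phase genes had log2 changes above 0 (camera adjusted p = 4.1e-08), with 3 higher adjusted over the list alone, Cks2 (131 to 162 CPM, log2 0.35), Cdk1 (83.6 to 108 CPM) and Gtse1 (6.66 to 9.23 CPM), and none over all genes. Of 43 S phase genes, 38 lay above 0 (adjusted p = 6.9e-05), with Gmnn at 31.9 and 37.0 CPM. Of 28 interferon-gamma response genes, 26 lay above 0 (adjusted p = 6.8e-04), with Cxcl10 at 131 and 164 CPM and Ifi47 at 44.9 and 53.3 CPM. Of 38 type I interferon response genes 29 lay above 0 and of 21 MHC class I genes 18 (adjusted p = 0.0152 each), with B2m at 2180 and 2609 CPM. With an estimated correlation the adjusted p = 0.838 for each of these 5 lists. The type I interferon list turned direction without control replicate 2 (camera adjusted p = 0.376) and was not called without shRNA replicate 2 (0.213). Without control replicate 2 the S phase (0.0705), interferon-gamma (0.302) and MHC class I (0.596) lists were not called either, nor were S phase (0.155) and interferon-gamma (0.263) without shRNA replicate 1 and MHC class I (0.104) without shRNA replicate 2. No member of the S phase, interferon or MHC class I lists passed by itself, over all genes or adjusted over the list alone.

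The 25 genes of the unfolded protein and integrated stress response had 20 above 0 (camera adjusted p = 0.0069), with Atf4, a transcription factor of that response, at 236 and 318 CPM and Ddit3 at 90.9 and 116 CPM, both higher adjusted over the list alone and neither over all genes. It had an adjusted p = 0.692 with an estimated correlation. Of 26 immediate early and heat shock genes, which enzymatic digestion can switch on, 20 lay above 0 (adjusted p = 8.7e-04), and 8 were higher and 1 lower adjusted over the list alone, none over all genes. The lower one, named after its value was seen, was the heat shock gene Hspa1a. Nr4a1 stood at 8.32 and 14.1 CPM and Fos at 229 and 299 CPM. Ribosomal protein genes (45 of 51 above 0, adjusted p = 1.6e-05) and cholesterol biosynthesis genes (21 of 24, adjusted p = 0.0174) were also called, with Msmo1 at 61.4 and 80.9 CPM. With an estimated correlation the adjusted p = 0.838 for these 3 lists. Nuclear genes of oxidative phosphorylation had 37 of 59 above 0 (adjusted p = 0.0174, and adjusted p = 0.692 with an estimated correlation), with Cycs at 113 and 158 CPM. The cholesterol list turned direction without shRNA replicate 2 (camera adjusted p = 0.315) and was not called without control replicate 2 (0.105). Calls were also lost for the unfolded protein response without control replicate 2 (0.0587) and shRNA replicate 1 (0.109), for the immediate early list without shRNA replicate 2 (0.243), and for oxidative phosphorylation without control replicate 1 (0.108) and shRNA replicate 1 (0.0865).

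All 13 mitochondrially encoded genes had log2 changes below 0 in tumour-like cells, with a median of -1.01 (camera adjusted p = 3.4e-11). Of these, 2 fell over all genes, mt-Cytb from 646 ± 65.9 to 305 ± 54.0 CPM (SD, n = 2 each; log2 -1.03, edgeR adjusted p = 0.043) and mt-Nd3 (log2 -0.71, adjusted p = 0.046), and 12 adjusted over the list alone. All 12 MHC class II genes lay below 0 (median -0.86, adjusted p = 1.1e-07), 2 fell over all genes, H2-DMa by 1.02 and H2-Ab1 by 0.79 on the log2 scale, and 8 adjusted over the list alone. With an estimated correlation the adjusted p = 0.829 for both lists. Free RNA could account for 9 of the 12 MHC class II genes. The semaphorins, plexins and plexin-B signalling genes had 29 of 37 below 0 (median -0.14, adjusted p = 0.0014, and adjusted p = 0.692 with an estimated correlation). In that list Plxna2, a receptor of class 6 semaphorins, fell from 7.17 ± 0.182 to 3.98 ± 0.495 CPM (log2 -0.80, adjusted p = 0.047), and adjusted over the list alone Cd72 also passed, although 89.1% of it could be free RNA. Without control replicates 1 and 2 in turn the edgeR adjusted p was 0.0807 and 0.210 for mt-Cytb, 0.162 and 0.206 for mt-Nd3 and 0.187 and 0.206 for Plxna2, and without control replicate 2 it was 0.162 for H2-DMa and 0.163 for H2-Ab1. Mitochondrial copies in the nuclear genome make the mitochondrial genes uncertain.

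Lists of hypoxia (camera adjusted p = 0.418), glycolysis (0.546), p53 targets (0.148), mesenchymal genes (0.748), epithelial genes (0.644), extracellular matrix (0.748), TGF-β targets (0.701), NF-κB targets (0.500), chemokines (0.624), angiogenesis (0.537) and checkpoint ligands (0.270) were not called in tumour-like cells. The tumour-like class was spread differently over clusters. Cluster 4 held 23% and 26.5% of it in the control and 4.03% and 5.33% in the shRNA libraries, cluster 3 held 23% and 23.6% against 9.05% and 19.8%, cluster 10 held 5.47% and 6.60% against 24.4% and 4.12%, cluster 6, with the stress genes Ddit3, Ero1l and Dnajb1 among its top genes, held 3.25% and 4.87% against 16.2% and 20.3%, and cluster 7, with Ier2 and Egr1, held 3.67% and 5.64% against 12.5% and 16.8%. Cluster 5, with Top2a, Ube2c and Cdk1, held 16.4% and 13.3% against 20.6% and 16.0%, and cluster 0, with Ifit3, Isg15 and Cxcl10, held 12.9% and 6.96% against 7.43% and 10.3%. The list values of tumour-like cells therefore do not show a change within cells. The 4 libraries weighed on the counts: without control replicate 1 there were 7 higher and 52 lower genes, without control replicate 2 there were 7 and 26, without shRNA replicate 1 there were 229 and 437, and without shRNA replicate 2 there were 344 and 392. DESeq2 called 83 higher and 180 lower, 31.6% higher against 15.2% in edgeR. Tested for a shared direction, fry called 0 of the 26 lists, where camera called 13. Its mixed test, for members that change either way, gave an adjusted p = 0.0050 for hypoxia, semaphorins and plexins and checkpoint ligands. It gave an adjusted p = 0.0068 for glycolysis.

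**Figure D3:**
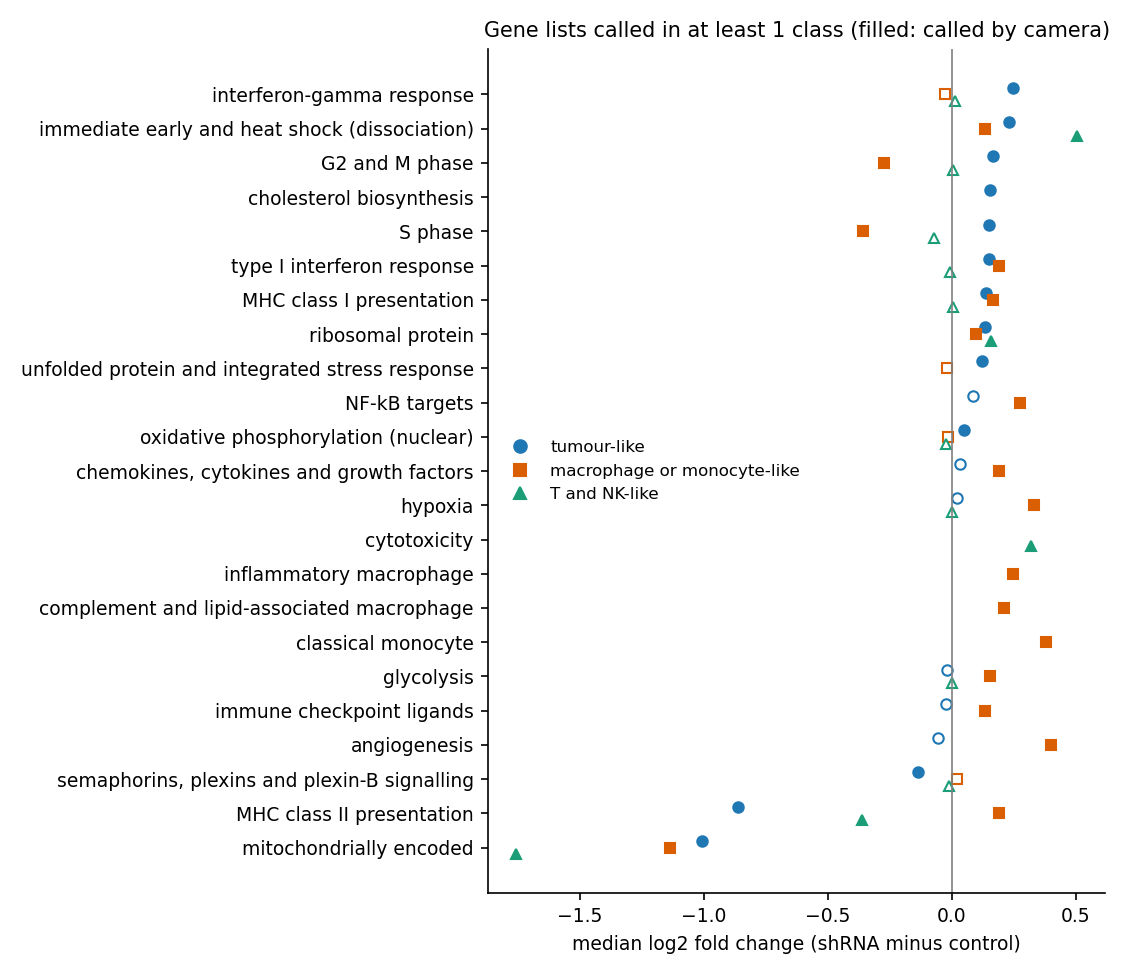
Median log2 change (shRNA minus control) of the members of each gene list in tumour-like, macrophage or monocyte-like and T and NK-like cells, with lists called by camera at the preset correlation set apart. Mitochondrially encoded genes had medians of -1.01, -1.13 and -1.75 in the 3 classes.

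Macrophage or monocyte-like cells of the shRNA tumours had less mitochondrially encoded RNA, and 20 genes changed in all, 4 higher and 16 lower out of 12479 (edgeR). Rab21 rose from 27.7 ± 0.279 to 46.0 ± 0.480 CPM (SD, n = 2 each; log2 0.81, SE 0.11, adjusted p = 0.021). The other 3 higher genes, named after their values were seen, were Gm12868, Gm26811 and the growth factor Areg, of which 86.7% could be free RNA of tumour cells. Hist1h2ae, a histone H2A gene with near-identical copies, fell from 107 ± 19.4 to 36.8 ± 4.22 CPM (log2 -1.47, SE 0.15, adjusted p = 0.0066). All 12 mitochondrially encoded genes tested fell, mt-Cytb from 1120 ± 117 to 411 ± 73.4 CPM (log2 -1.37, adjusted p = 0.0066), mt-Atp8 by 1.30, mt-Nd1 by 1.17 and mt-Co1 by 1.02 on the log2 scale. Without control replicates 1 and 2 in turn the edgeR adjusted p was 0.144 and 0.312 for Rab21, 0.0606 and 0.110 for mt-Cytb, 0.0677 and 0.0715 for mt-Atp8, 0.0606 and 0.0870 for mt-Nd1 and 0.159 and 0.219 for mt-Co1, without control replicate 2 it was 0.0715 for Hist1h2ae, and without shRNA replicate 1 it was 0.0782 for mt-Co1. The mitochondrial list had a camera adjusted p = 5.3e-21, and an adjusted p = 0.722 with an estimated correlation.

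The cell cycle lists stood lower in macrophage or monocyte-like cells as a class, and so did the share of a cluster marked by histone genes. Cluster 19, with Hist1h2ae and other histone genes among its top genes, held 5.99% and 8.70% of the class in the control and 3.53% and 2.88% in the shRNA libraries, so the values do not show a change within cells. Of 43 S phase genes 40 lay below 0 (median -0.36, camera adjusted p = 2.6e-14), and 16 were lower adjusted over the list alone but none over all genes. Rrm2, a subunit of ribonucleotide reductase, stood at 20.2 and 10.7 CPM, E2f8 at 13.2 and 7.10 CPM, and Tyms, thymidylate synthase, at 28.1 and 16.7 CPM. Of 51 G2 and M phase genes 44 lay below 0 (adjusted p = 3.1e-09), with 4 lower adjusted over the list alone, namely Top2a (140 to 86.0 CPM), Mki67 (88.7 to 57.1 CPM), Nusap1 and Lbr. Both lists had an adjusted p = 0.722 with an estimated correlation.

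Lists of hypoxia, inflammation and antigen presentation stood higher in the class, whose cells were also spread differently over clusters. Cluster 18, with Mmp12, Il1rn and Nos2 among its top genes, held 14.7% and 12.7% of the class in the control and 20.6% and 26.4% in the shRNA libraries. Cluster 14, with C1qa and Apoe, held 47.9% and 61.3% against 45.0% and 44.9%, and the monocyte cluster 12, with Plac8, Hp and Ms4a4c, held 16.3% and 8.95% against 23.4% and 14.1%. Of 29 hypoxia genes 25 lay above 0 (camera adjusted p = 3.3e-06), 8 higher adjusted over the list alone, with Ndrg1 at 78.4 and 113 CPM, Ero1l at 124 and 171 CPM and Bhlhe40 at 42.8 and 61.8 CPM. Of 19 glycolysis genes 16 lay above 0 (adjusted p = 0.0051), 2 of them higher adjusted over the list alone, Aldoc and Hk2. Of 16 classical monocyte genes 14 lay above 0 (adjusted p = 9.4e-05), with 5 higher adjusted over the list alone, Mgst1 (86.4 to 122 CPM), Hp, S100a4, Ms4a4c and, named after its value was seen, S100a6. Of 25 NF-κB targets 22 lay above 0 (adjusted p = 1.3e-04), with Tnfaip2 (109 to 170 CPM), Cxcl1 and Tnf (41.9 to 58.6 CPM) higher and Nfkbiz lower adjusted over the list alone. These 4 lists had an adjusted p = 0.722 with an estimated correlation, and no member passed over all genes. The glycolysis list was not called without control replicate 2 (camera adjusted p = 0.199), nor NF-κB targets without shRNA replicate 1 (0.112).

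Type I interferon response genes had 32 of 38 above 0 (camera adjusted p = 1.8e-04) and MHC class I genes 18 of 21 (adjusted p = 0.0020), with H2-Q6, H2-Q7 and H2-T22 higher adjusted over the list alone. H2-Q6 and H2-Q7 are close copies and uncertain, and stood at 53.5 and 81.9 CPM and at 206 and 288 CPM. Of 21 complement and lipid-associated macrophage genes 15 lay above 0 (adjusted p = 0.0041), with 6 higher adjusted over the list alone, among them the lysosomal protease Ctsl (336 to 492 CPM) and the haem oxygenase Hmox1 (299 to 428 CPM). Chemokines (28 of 41 above 0, adjusted p = 0.0043), checkpoint ligands (12 of 15, adjusted p = 0.0183), inflammatory macrophage genes (12 of 18, adjusted p = 0.0236), MHC class II (11 of 12), immediate early (21 of 26) and angiogenesis genes (15 of 20, adjusted p = 0.0258 for each of the 3) were called as well, with Il1b at 83.1 and 122 CPM, Lgals3 at 2717 and 3680 CPM, H2-Ab1 at 4711 and 5812 CPM, and Vegfa at 47.5 and 65.3 CPM. With an estimated correlation the adjusted p = 0.722 for each of these 9 lists. Ribosomal protein genes had 40 of 51 above 0 (adjusted p = 0.0112, and adjusted p = 0.878 with an estimated correlation).

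Each of these lists of macrophage or monocyte-like cells lost its call with at least 1 library left out. The chemokine list turned direction without shRNA replicate 1 (camera adjusted p = 0.908) and the ribosomal list without control replicate 1 (0.851), and the ribosomal list was not called without shRNA replicate 2 (0.905). Without control replicate 2 calls were lost for type I interferon (0.641), immediate early (0.120), angiogenesis (0.249), checkpoint ligand (0.120) and inflammatory macrophage genes (0.120). Without shRNA replicate 1 they were lost for type I interferon (0.112), MHC class I (0.634), MHC class II (0.0949), angiogenesis (0.538), checkpoint ligand (0.245), inflammatory macrophage (0.538) and complement and lipid-associated genes (0.252). Without control replicate 1 they were lost for MHC class II (0.870) and complement and lipid-associated genes (0.0598), and without shRNA replicate 2 for MHC class II (0.165) and immediate early genes (0.951).

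Interferon-gamma response (camera adjusted p = 0.855), nuclear oxidative phosphorylation (0.855), the unfolded protein response (0.982), TGF-β targets (0.394), semaphorins and plexins (0.982) and alternatively activated macrophage genes (0.982, with a median of 0.09 and a mean of 0.42 but a test direction below 0) were not called. The count of 20 changed genes was 2 without control replicate 1, of which 1 (Hist1h2ae) is among the 20, 7 without control replicate 2, of which 0 are among the 20, 72 without shRNA replicate 1 and 218 without shRNA replicate 2, and the 17 lists called were 11 without control replicate 2 and 10 without shRNA replicate 1. With genes that overlap ribosomal RNA or are mitochondrial left out, edgeR called 0 genes, with 1155 at an unadjusted p under the limit, while on all genes DESeq2 called 65, 55.4% of them higher against 20% in edgeR. Fry called 0 of the 25 lists.

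T and NK-like cells of the shRNA tumours carried, as a class, more Gzmd, Gzme and immediate early RNA, with 22 genes higher and 17 lower out of 8011 (edgeR). Gzme rose from 18.9 ± 1.14 to 77.4 ± 25.8 CPM (SD, n = 2 each; log2 2.00, SE 0.28, adjusted p = 5.4e-05) and Gzmd from 55.1 ± 11.1 to 172 ± 19.6 CPM (log2 1.62, SE 0.18, adjusted p = 1.9e-07). These granzymes are close paralogs on chromosome 14 (56117626 to 56120625 and 56129556 to 56132608), so the split of reads between them is uncertain. Spp1, which encodes osteopontin, rose from 329 ± 77.1 to 780 ± 84.1 CPM (log2 1.28, adjusted p = 3.4e-07), with 29.7% of it expected from free RNA. Car2, a carbonic anhydrase, rose by 1.14 (adjusted p = 0.016) and Ppp2cb by 1.07 (adjusted p = 0.045). Nkain2 fell from 412 ± 16.6 to 187 ± 20.1 CPM (log2 -1.13, adjusted p = 3.4e-07), and Ube2m, a NEDD8-conjugating enzyme, fell by 0.80 and Hist1h2ae by 0.70 on the log2 scale. NK cells, with Car2, Tyrobp and Gzmc among their top genes, were 9.68% and 14.3% of the class in the control and 24% and 16.8% in the shRNA libraries. A sub-cluster with Gzmd and Gzme among its top genes held 3 of 372 and 3 of 265 cells in the control libraries. In the shRNA libraries it held 8 of 471 and 5 of 914 cells, so its share of the class was not larger in both.

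The calls of Gzmd, Gzme, Spp1 and Nkain2 in T and NK-like cells held with any library left out. Without control replicate 1 the edgeR adjusted p was 0.566 for Car2, 0.0603 for Ppp2cb, 0.17 for Ube2m and 0.0605 for Hist1h2ae. For Ppp2cb it was 0.196 without control replicate 2, 0.159 without shRNA replicate 1 and 0.281 without shRNA replicate 2, so its call needs all 4 libraries. Without shRNA replicate 1 it was 0.159 for Ube2m and 0.189 for Hist1h2ae, and without shRNA replicate 2 it was 0.0552 for Ube2m, 0.103 for Hist1h2ae and 0.0685 for Car2.

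Of 23 cytotoxicity genes 18 lay above 0 (camera adjusted p = 9.5e-05). The share of NK cells was higher in both shRNA libraries but did not pass the test (edgeR adjusted p = 0.343). Gzmd and Gzme rose over all genes, and 4 were higher adjusted over the list alone, these and the cytokines Ifng (354 to 499 CPM) and Tnf (39.3 to 59.0 CPM). Of 26 immediate early and heat shock genes 25 lay above 0 (adjusted p = 6.1e-12), of which 7 rose over all genes and 16 adjusted over the list alone. Fos rose from 479 ± 56.8 to 981 ± 173 CPM (SD, n = 2 each; log2 1.05, edgeR adjusted p = 4.1e-06), Jun from 459 ± 12.6 to 876 ± 105 CPM (log2 0.96, adjusted p = 7.0e-06) and Klf2 from 219 ± 18.7 to 363 ± 1.10 CPM (log2 0.76, adjusted p = 5.6e-04). Hspb1 stood at 0.984 ± 1.39 and 20.2 ± 5.28 CPM (adjusted p = 3.1e-04). For both lists the adjusted p = 0.440 with an estimated correlation. The ribosomal protein list had 44 of 51 above 0 (adjusted p = 0.0027, and adjusted p = 0.998 with an estimated correlation), with Rps27 and Rpl32 among those higher adjusted over the list alone, and was not called without control replicate 1 (0.347) or shRNA replicate 1 (0.322).

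All 11 mitochondrially encoded genes lay below 0 in T and NK-like cells (median -1.75, camera adjusted p = 2.9e-18, and adjusted p = 0.461 with an estimated correlation), and mt-Cytb (log2 -1.95) and mt-Nd3 (log2 -1.57) fell over all genes, 9 adjusted over the list alone. All 9 MHC class II genes lay below 0 (adjusted p = 2.6e-04, and adjusted p = 0.440 with an estimated correlation). H2-Eb1, Cd74 and H2-Aa fell over all genes, by 1.05, 0.69 and 0.95 on the log2 scale, and H2-Ab1 also adjusted over the list alone, and free RNA of other cells could account for 98.1%, 96.5%, 92.1% and 89.8% of them. Without shRNA replicate 1 the edgeR adjusted p was 0.0746 for H2-Eb1, 0.336 for Cd74 and 0.267 for H2-Aa, and without control replicate 2 it was 0.352 for H2-Aa. Macrophage markers stood in T and NK-like cells at 2.16% and 2.19% of their macrophage level in the control and at 0.624% and 0.971% in the shRNA libraries. Of 13 naive and memory T-cell genes 9 lay above 0 (adjusted p = 0.17). In that list Klf2 rose over all genes, and Dapl1, Ccr7 and Cd27, named after their values were seen, also passed adjusted over the list alone, Cd27 downward. T-cell exhaustion and regulatory T-cell genes were not called (adjusted p = 0.945 each), nor were the interferon, MHC class I, hypoxia, glycolysis, oxidative phosphorylation, cell cycle and semaphorin lists (0.274 to 0.996).

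**Figure D4:**
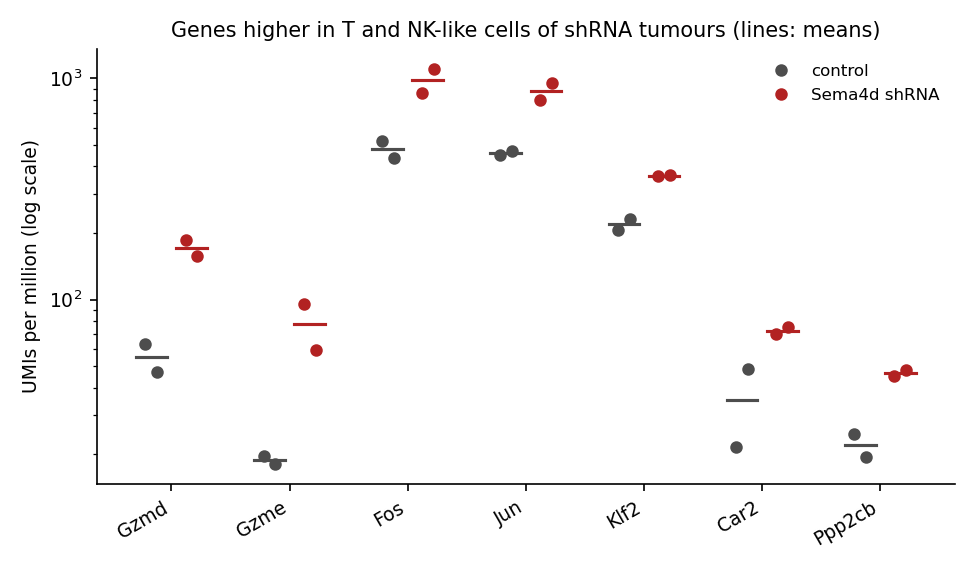
Level in CPM of Gzmd, Gzme, Fos, Jun, Klf2, Car2 and Ppp2cb in T and NK-like cells, with a point per library for the control and shRNA groups. Gzmd stood at a mean of 55.1 CPM in the control and 172 CPM in the shRNA libraries.

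The 39 genes of T and NK-like cells became 80 without control replicate 1 and 90 without control replicate 2, and 20 with low-UMI and mixed clusters added. DESeq2 called 14 higher and 18 lower, 43.8% higher against 56.4% in edgeR, and fry called 0 of the 18 lists, where camera called 5.

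The shRNA effect was compared between cell classes for the named genes only. Between macrophage or monocyte-like and tumour-like cells, the edgeR interaction test called 59 of 128 genes, and between T and NK-like and tumour-like cells 17 of 90. These genes were named for a large change or a small p in a class, which favours a difference between classes, so the counts say nothing of genes in general. Among them, E2f8 differed by -1.17 and Top2a by -0.86 on the log2 scale between macrophage or monocyte-like and tumour-like cells, and H2-Ab1, largely free RNA in tumour-like cells, by 1.19. In T and NK-like cells the difference from tumour-like cells was 0.67 for Fos, 0.77 for Jun, 0.82 for Klf2 and -0.90 for mt-Cytb. Without control replicate 2, 37 and 10 genes were called in these comparisons.

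Mitochondrially encoded RNA was lower in every class tested. It made up 0.715% and 0.676% of UMIs in tumour-like cells of the control libraries against 0.305% and 0.421% in the shRNA libraries, 1.39% and 1.38% against 0.546% and 0.669% in macrophage or monocyte-like cells, and 1.55% and 1.23% against 0.294% and 0.518% in T and NK-like cells. This difference moved with the groups beside every gene list above.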

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

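Of the tests below, only that of damaged cells of low depth was written down before its result was known, and the other tests were chosen after results had been seen. Each gene here stands out because the edgeR interaction test found that its shRNA effect differs between tumour-like cells and another class. This holds for 59 of 128 named genes for macrophage or monocyte-like cells and for 17 of 90 for T and NK-like cells. The genes were named for a large change or a small p in a class, which favours such a difference, so these counts overstate how often classes differ. Values are the log2 change in the other class minus that in tumour-like cells.

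For macrophage or monocyte-like cells, Sema4d differed by 0.75. Cell cycle genes gave Gmnn (-0.57), Prim1 (-0.50), Rrm1 (-0.54), Dtl (-1.21), Cdk1 (-0.56), Gtse1 (-0.78), Nusap1 (-0.86), E2f8 (-1.17), Rrm2 (-1.14), Tyms (-0.82), Hells (-0.72), Top2a (-0.86), Mki67 (-0.66), Lbr (-0.68) and Hist1h2ae (-1.18). Of 10 mitochondrially encoded genes tested, 4 were further down, mt-Cytb (-0.32), mt-Nd3 (-0.41), mt-Atp6 (-0.31) and mt-Nd1 (-0.34), and the others were not called, with mt-Nd6 (0.33) and mt-Nd5 (0.26) above 0. MHC class II genes and their regulator Ciita differed upward, with Ciita (1.16), H2-DMa (1.09), H2-Ab1 (1.19), Ctss (1.18), H2-Aa (1.15) and H2-Eb1 (1.18). Among cytokine, chemokine and NF-κB genes the values were Cxcl10 (-0.59), Tnf (1.29), Tnfaip2 (0.52), Nfkbiz (-0.48), Hbegf (0.41), Ccl6 (1.29), Cxcr4 (0.96), Cxcl2 (1.5), Il1b (1.15) and Cd40 (0.95). Hypoxia and glycolysis genes gave Ero1l (0.40), Ddit4 (0.42), Aldoc (0.71) and Pfkp (0.45). Genes of monocytes and phagocytes gave Arg1 (1.31), Fcer1g (1.17), Lgals3 (0.58), Ctsl (0.59), Lipa (0.46), Hp (1.01) and Ms4a4c (1.15). The remaining genes were Ybx3 (-0.31), Gstp1 (0.65), Heg1 (1.10), Cd72 (0.99), Slfn5 (1.29), Cycs (-0.31), Ndufa12 (-0.27), Ier2 (-0.37), Fos (-0.35), Btg2 (-0.57), Sema6d (1.5) and H2-Q6 (0.72). In tumour-like cells, 15 of 48 chemokine, cytokine and growth factor genes, 5 of 25 NF-κB targets and 9 of 12 MHC class II genes were mostly free RNA. So were 3 of 37 semaphorin and plexin genes, Cd72 among them. For such genes the difference can reflect less free macrophage RNA in tumour-like cells. The macrophage share of all UMIs changed by -1.20 on the log2 scale.

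For T and NK-like cells, 5 of 6 mitochondrially encoded genes tested were called, mt-Cytb (-0.90), mt-Nd3 (-0.85), mt-Atp6 (-0.85), mt-Co2 (-0.89) and mt-Nd1 (-0.80). Of 7 immediate early and heat shock genes tested 4 were called, Fos (0.67), Jun (0.77), Klf2 (0.82) and Hspb1 (3.72), the last of which rests on control counts near 0. The remaining genes were Fcer1g (1.69), Cd72 (1.88), Ctss (0.71), Cycs (-0.47), Spp1 (1.20), Car2 (1.71), Ube2m (-0.54) and Tnf (1.38). Less free RNA could give 93.8% of the fall of Fcer1g in tumour-like cells. Cd72 stood at only 2.74 and 1.36 CPM in tumour-like cells, most of which could also be free RNA, and at 14.3 and 26.2 CPM in T and NK-like cells.

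Genes of macrophages such as Arg1, Fcer1g and H2-Ab1 were lower in tumour-like cells of the shRNA tumours. Less free macrophage RNA in the droplets could account for most of this, since it gave a median of 90.7% of the fall in CPM over the 49 lower genes with a higher control level in macrophage or monocyte-like cells, taken without regard to their share of free RNA. Over the 38 of them not on the list of macrophage markers from which free RNA was estimated, the median was 84.0%. A change in the tumour cells' own expression cannot be told apart for part of the 49 genes. Free RNA gave 57.2% of the fall at their first quartile, and 28.6% at that of the 38 genes. Free RNA gave 3.45% of the fall of Tsc22d3 and 4.21% of that of mt-Cytb. The estimate rests on macrophage markers counted in tumour-like cells, so it cannot separate free RNA from doublets with macrophages left in the class. The doublet rule also differed between the groups. With doublet calls kept, 42 genes were lower, 22 of them called mostly free RNA, against 67 and 38 in the main test. With the same doublet share left out of every library these were 64 and 34.

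Mitochondrially encoded RNA such as mt-Cytb was lower in the shRNA libraries in every class tested. Damaged cells of low depth in the control libraries are not a likely cause within these classes, as at least 93.8% of the change was left in the deeper cells. The test did not cover the unnamed cluster of few UMIs, whose top 10 genes were all mitochondrially encoded, at a median share of 2.43%. That cluster held 6.61% and 3.99% of the control and 1.60% and 2.24% of the shRNA cells. A single factor of handling or library preparation common to all cells of a library would give the same change in each class, but the log2 ratio of the mitochondrial share to that of tumour-like cells in the same library differed between the groups by -0.24 (SE 0.09) for macrophage or monocyte-like and by -0.87 (SE 0.22) for T and NK-like cells, without overlap of the libraries. With 2 libraries per group an exact permutation test cannot go below 0.333, so such a single factor is not excluded. A factor of that kind that acts more strongly on some classes was not tested. The shRNA itself cannot be told apart from any other cause that follows the groups, since both shRNA libraries lay below both controls in all 3 classes.

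Of 38 genes changed in tumour-like cells, mostly of own RNA there, and tested in macrophage or monocyte-like cells, 33 changed in the same direction. Rab21 and Ppp2cb were among them, and the edgeR interaction test called no difference for these 2 (adjusted p = 0.779 and 0.384). Free RNA of tumour cells counted in macrophages cannot be told apart as a cause for part of the 33 genes. Over all of them it gave a median of 10.7% of the change in CPM in macrophage or monocyte-like cells but 65.2% at the third quartile. It gave 8.55% for Rab21 and 26.6% for Ppp2cb, but 62.0% for H19 and 93.0% for Prkcdbp. A difference between the libraries of the 2 groups that acts on all cell classes could also be the cause and stays open. Of the 30 genes of mostly own RNA in both classes, 26 changed in the same direction. Over the 30, the median ratio of the log2 change in macrophage or monocyte-like cells to that in tumour-like cells was 0.717, below the range set for such a difference. The genes were chosen for passing the test in tumour-like cells, which favours a lower ratio, so 0.717 does not argue against it. In T and NK-like cells that ratio was 1.03, inside the range, with 17 of 20 genes in the same direction.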

How the results depend on the processing

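The tests with low-UMI and mixed clusters added, nuclear-rich clusters, ribosomal and mitochondrial genes or free-RNA genes left out, equal doublet shares and bias-adjusted dispersions were chosen after results had been seen. Of the main results, 221 values under alternatives fixed in advance and 72 under later ones stayed the same. For a test this means that it kept its direction and side of the threshold. For a count of genes or lists it means only that the count stayed within 1.5 times. Of the other main results, 35 and 5 counts moved by over 1.5 times, 15 turned direction, 3 came to pass and 1 no longer passed. Of the values of single genes and lists, 2193 and 985 kept their direction and side of the threshold. Among these single genes and lists, 204 and 11 came to pass the test, 199 and 24 no longer passed, and 8 and 1 turned direction. For changes not shown by the construction of the alternative, the cause was not tested.

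The 12 genes higher in tumour-like cells were 83 with DESeq2, 290 without the low-count filter, 7 with doublet calls kept, 7 with bias-adjusted dispersions and 7 to 344 with a library left out. The 67 lower genes were 180, 462 and 42 in the first 3 of these, 29 without free-RNA genes and 26 to 437 with a library left out. The 20 genes changed in macrophage or monocyte-like cells were 65 with DESeq2, 378 without the filter, 31 with equal cells, 34 without nuclear-rich clusters, 0 in edgeR without ribosomal and mitochondrial genes (1155 at an unadjusted p under the limit) and 2 to 218 with a library left out. The 39 of T and NK-like cells were 88 without the filter, 20 with low-UMI and mixed clusters and 50 to 90 with a library left out. A group left with 1 library is assumed to vary like the other group.

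Sema4d in tumour-like cells ranged from -0.86 to -0.31 with a library left out, and at -0.49 without control replicate 2 no longer passed. Its difference between T and NK-like and tumour-like cells ranged from -0.0126 to 0.45. Cd72 in macrophage or monocyte-like cells was -0.00772 with doublet calls kept, -0.00219 with equal doublet shares and -0.16 to 0.21 with a library left out. Genes that differ between classes were 37 to 62 for macrophage or monocyte-like and 10 to 17 for T and NK-like cells.

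Camera called 13, 17 and 5 lists in tumour-like, macrophage or monocyte-like and T and NK-like cells. With an estimated correlation these were 0, 0 and 0, and with fry, tested for a shared direction, 0, 0 and 0. With a library left out, 7 to 13 lists were called in tumour-like and 10 to 16 in macrophage or monocyte-like cells. The adjusted p of lists that turned direction there ranged from 7.5e-11 to 0.376 for type I interferon response and 9.4e-10 to 0.315 for cholesterol biosynthesis in tumour-like cells, and from 3.0e-05 to 0.908 for chemokines and 3.5e-06 to 0.905 (0.851 without control replicate 1, where it turned) for ribosomal protein genes in macrophage or monocyte-like cells.

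The log2 change of the immune T and NK-like share was 1.62 at resolution 2 and 1.68 with TMM factors, both past the threshold. With a library left out, dendritic-like cells ranged from -0.78 to 0.11 of all cells and from -0.11 to 0.61 of immune cells, endothelial-like cells from -0.0316 to 0.56, fibroblast-like cells from -0.0215 to 1.89, immune neutrophil-like cells from -1.41 to 0.0785, CD8 T cells from -0.43 to 0.31, cycling cells from -0.11 to 0.14 and regulatory T cells from -0.96 to 0.23. CD8 T cells were 0.0174 with doublet calls kept and 0.0676 at resolution 0.5. Cycling cells were -0.00874 with doublet calls kept, -0.000630 with stricter cell limits and -0.0143 with TMM factors.

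With the replicate number as a block, 32 genes changed in macrophage or monocyte-like, 16 were higher and 92 lower in tumour-like and 33 changed in T and NK-like cells. Libraries with the same number did not deviate together, with correlations of -0.00728, 0.0743 and -0.0152 in tumour-like, macrophage or monocyte-like and T and NK-like cells.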

Other observations

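No tests were chosen for this part, and its values come from classes with too few cells to test. Dendritic-like cells carried Sema4d at 96.8 ± 9.50 CPM in control and 58.2 ± 10.1 CPM in shRNA tumours (SD, n = 2 each), and neutrophil-like cells at 77.6 ± 37.3 and 104 ± 8.81 CPM. Fibroblast-like cells held 11.5 ± 0.584 and 3.54 ± 2.33 CPM, on 7 UMIs in all. The receptor Plxnb2 stood at 98.7 ± 17.3 and 59.0 ± 2.65 CPM in fibroblast-like cells, 37.5 ± 6.05 and 34.3 ± 7.38 CPM in dendritic-like cells 33.0 ± 7.26 and 22.8 ± 17.4 CPM in endothelial-like cells, on 25 UMIs, and 40.7 ± 33.4 and 78.2 ± 55.2 CPM in neutrophil-like cells, on 34 UMIs. Cd72, the B-cell and myeloid receptor, stood at 53 ± 6.96 and 54.7 ± 15 CPM in dendritic-like cells.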
